A study of Mus musculus with 2 samples.

How the data were processed

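The series holds total RNA sequencing of 2 biological replicates of the G1E line, made from 1 ng of RNA longer than 200 nucleotides per the labels. The extraction protocol that the labels link to is named for both G1E and the related ER4 cells. For each library a gene table and a transcript table were used. Per the file headers, the authors deposited estimated counts (expected counts, not normalised and not all whole). Per the file headers, the deposited TPM values are scaled to a fixed sum over all transcripts and come as a maximum-likelihood and a posterior mean estimate. Per the file headers, the deposited FPKM values are scaled to transcript length and library size. Per the file headers, the deposited bounds of other columns are credibility intervals of TPM. Per the file headers, the isoform share is a deposited percent of the gene's TPM on each transcript. The deposited file records name the mm10 assembly and GENCODE M4. The aligner, the quantifier and their versions are not given in the sources used here.

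Gene names, types and positions came from GENCODE M21 on GRCm38, the same assembly with a later annotation, matched on identifiers without their version. Of 43346 genes 42462 matched, and the 884 that did not match held 0.0818% and 0.0571% of the estimated count. The 97 spike-in entries and 26248 entries named only by a number stayed out of the tests of genes. The entries named by a number held 3 and 7 counts. Of 289 listed gene entries, 10 (Ahsp, Hbb-b1, Hbb-b2, the older names Epb49 and Emr1, Snhg1 and Rn45s) were not analysed here.

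Levels were given as TPM with the mean and SD over 2 libraries, and a gene was detected at a TPM of at least 1 in both. Logarithms used a pseudocount of 1 TPM. Because the labels give 1 group, no group was tested. The libraries were compared with a two-sided exact binomial test per gene on estimated counts rounded to whole numbers, against the ratio of TMM effective library sizes from edgeR 4.0.16 (R 4.3.3). A gene passed at a Benjamini-Hochberg adjusted p under 0.05 and at least a 2-fold ratio, among genes with at least 10 counts over both libraries. Ratios have exact 95% Clopper-Pearson intervals, and a gene at 0 was set to 3 counts for a lower bound. These tests and intervals cover counting error in a pair of libraries, which amplification from 1 ng of RNA can exceed. The common dispersion came from edgeR with an intercept only. Gene lists were ranked among 10000 random lists, drawn from expressed genes for levels and matched in 20 expression bins for ratios. Python 3.11.15, SciPy 1.17.1, pandas 2.3.3, NumPy 2.4.6, matplotlib 3.10.9, DESeq2 1.42.0 and BLAST 2.17.0 were used besides.

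The library comparison was tested on simulated data with the means and sizes of these libraries and 200 changed genes among 11901 tested. It recovered 34.0% of 50 genes changed 2-fold, 100% of 50 each at 3-, 8- and 20-fold, and called 0 of 11701 unchanged genes. These simulated counts held counting error only, and changes were placed in genes with at least 100 counts over both libraries. The 0 calls therefore do not measure false calls from spread between replicates. In a separate simulation with such spread, a coefficient of variation of 0.2 was recovered as 0.200.

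Depth was 31649878 estimated counts in replicate 1 and 40597614 in replicate 2, of which 8513094 and 7669565 fell on nuclear protein-coding genes. The 20 gene lists, the tests and most alternatives were chosen before the data were examined. The lists covered GATA factors and partners, GATA1-repressed and GATA1-activated genes, globins, haem, red cell membrane, iron, cytokine receptors, cell cycle, apoptosis, 6 sets of markers of other cell types, stress genes, reference genes, structural RNAs and sex-linked genes. The named genes were Gata1 and Gata2, up to 4 members with the highest and 3 with the lowest mean TPM of each list, the 10 nuclear protein-coding genes with the highest mean TPM, and the 5 largest ratios in each direction among genes that passed with a mean count of at least 100. A few genes that this rule names are not reported here. Alternatives were other scalings, filters, pseudocounts, estimates (FPKM, posterior mean TPM, CPM), a negative binomial test, and leaving out each library.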

Results

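G1E is an immortalised mouse erythroid progenitor line that is labelled as lacking Gata1, the gene of the transcription factor that drives erythroid maturation. Total RNA longer than 200 nucleotides was sequenced from 2 biological replicates of these cells (labelled strain C57BL/6J, male), each from 1 ng of RNA, with ERCC spike-in transcripts in the libraries. The labels define 1 group, so levels are described and the libraries are compared with each other. The estimated counts summed to 31649878 in replicate 1 and 40597614 in replicate 2. A count of 0 therefore allowed up to 0.0948 and 0.0739 CPM, respectively. All intervals and floors cover counting error only.

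Ribosomal RNA filled most of both libraries. Gm42418, a non-coding gene annotated on chromosome 17 (39846958 to 39848788, GRCm38) and known to overlap a ribosomal RNA repeat, took 52.6% of the estimated count in replicate 1 and 40.3% in replicate 2. The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 took 14.6% and 35.4%, and mt-Rnr2 alone had 2652063 and 9543762 counts. Nuclear protein-coding genes other than histones took 26.6% and 18.7% (22.7% ± 5.58, SD, n = 2). Mitochondrial mRNAs took 3.03% and 3.11% (3.07% ± 0.0546, SD, n = 2). Nuclear copies of these mRNAs were classed as pseudogenes, so this share and its SD depend on how shared reads were divided. Gm10925 had 110017 and 37588 counts and was identical to mt-Atp6 over 678 nucleotides in BLAST. Gm28661 had 22413 and 46535 and was identical to mt-Co2 over 681. Both were named after their values were seen. With these class shares, TPM values were 1.55-fold higher in replicate 1 for the median gene, with a log2 ratio of -0.63 for replicate 2 over replicate 1. The SDs of TPM given below include this shift, so they do not rank genes by replicate agreement. Malat1 had 903 ± 8.09 TPM but a ratio of 1.63 after TMM scaling. Eef1a1 had 3579 ± 1225 TPM but a ratio of 1.03.

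**Figure D1:**
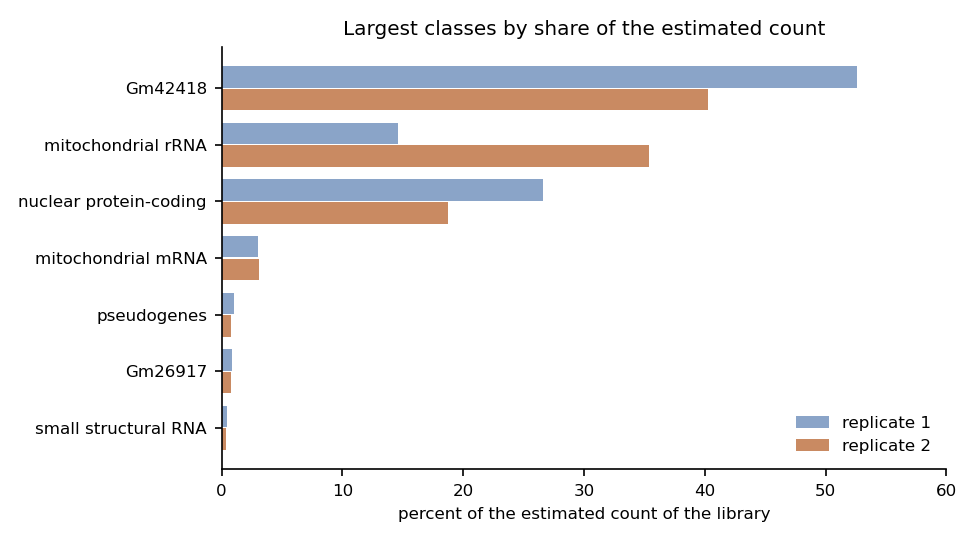
Percent of each library's estimated count (horizontal axis, from 0) taken by the 7 largest classes, with 1 bar per library. Mitochondrial ribosomal RNA took 14.6% in replicate 1 and 35.4% in replicate 2.

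The most abundant nuclear protein-coding transcripts encoded translation factors, ribosomal proteins and a glycolytic enzyme. Eef1a1, a translation elongation factor, had 3579 ± 1225 TPM (SD, n = 2), and Gapdh, a glycolytic enzyme, had 2028 ± 793 TPM. Lars2 (1741 ± 61.4 TPM) and Hist1h4d, a histone H4 gene (1582 ± 621 TPM), followed. Whether the reads assigned to Lars2 (142551 and 187546 estimated counts) came from its mRNA was not tested. Rpl4, Rpl17, Rps26, Pabpc1 and Rpl12 were also among the first 10, from 1429 TPM for Rpl4 down to 738 TPM for Rpl12. In total 9161 of 43346 genes reached a TPM of 1 in both libraries, 8345 of them among the 21461 nuclear protein-coding genes. The 14 reference genes were all detected, with a median of 137 ± 30.6 TPM (SD, n = 2).

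Transcripts of both GATA factors of erythroid progenitors were present, which bears on the label of the line. Gata2 (ENSMUSG00000015053.10, chromosome 6, 88193891 to 88207032) had 52.8 and 29.5 TPM in replicates 1 and 2. Gata1 (ENSMUSG00000031162.10, chromosome X, 7959260 to 7978071) had 21.96 and 12.51 TPM, from 798 and 649 estimated counts. Their log2 ratio was 1.20 ± 0.04 (SD, n = 2), a Gata2 level 2.30-fold that of Gata1 after adding 1 TPM to each. A gene-level count does not show whether the transcript can still be translated, and an exact sign-flip test over 2 libraries cannot give a two-sided p below 0.5. Gata2 was the higher of the pair in both libraries.

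Among the 22 GATA factors and haematopoietic partners, 20 were detected in both libraries, with a median of 25.6 ± 8.53 TPM (SD, n = 2). Gfi1b, a repressor required for erythroid development, had 97.3 ± 35.9 TPM. Myb (63.1 ± 23.3 TPM), Tcf12 (60.1 ± 22.8 TPM) and Nfe2 (49.5 ± 22.1 TPM) followed, while Fli1 (0.90 ± 0.17 TPM), Erg (1.14 ± 0.205 TPM) and Gata3 (2.91 ± 1.55 TPM) were lowest. Sox6, a regulator of globin genes, was the only member of the 22 to pass both the adjusted p and the 2-fold limit, 7.18-fold higher in replicate 2 (95% interval 6.19 to 8.36). It was named after its value was seen.

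Genes that GATA1 is known to repress were abundant, and their ratios between the libraries stayed under 2-fold. All 7 were detected, with a median of 41.3 ± 16.3 TPM (SD, n = 2), and none passed the test between the libraries. Myc (ratio of replicate 2 over replicate 1 0.786, 95% interval 0.744 to 0.830) and Gata2 (0.866, 0.823 to 0.911) were lower in replicate 2 beyond counting error but within the 2-fold limit. Kit, the stem cell factor receptor, had 145 ± 42.7 TPM, Myc 58.6 ± 25.3 TPM, Vim 38.6 ± 12.5 TPM, Lyl1 23.5 ± 6.98 TPM and Hhex 10.9 ± 3.04 TPM. Their median log2 ratio of replicate 2 over replicate 1 was -0.02.

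Genes that GATA1 is known to activate separated the libraries. Of 25 measured members, 11 were higher in replicate 2 and 0 in replicate 1, and 11 and 0 when adjusted over the list alone. Slc4a1, the red cell anion exchanger, had 115 counts in replicate 1 and 10387 in replicate 2, a 101-fold difference (95% interval 84.3 to 123). The alpha globins Hba-a1 and Hba-a2 together were 11.96-fold higher in replicate 2 (11.2 to 12.8), and the beta globins Hbb-bs and Hbb-bt together 20.8-fold higher (18.7 to 23.1). Alas2, the erythroid enzyme of the first step of haem synthesis, was 8.29-fold higher (6.26 to 11.2), and the blood group gene Rhd 21.4-fold higher (13.7 to 35.5).

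The remaining 14 measured members of that list did not pass the test. Car1, a carbonic anhydrase, had 199 ± 82.3 TPM (SD, n = 2) and a ratio of 0.855 (95% interval 0.822 to 0.889). Klf1, an erythroid transcription factor, had a ratio of 1.06 (0.927 to 1.22). Btg2, an anti-proliferative gene, was 1.79-fold higher in replicate 2 (1.47 to 2.19), below the 2-fold limit, and Icam4 had 8 and 16 counts. Both were among the lowest members, with 3.21 ± 0.325 and 0.585 ± 0.148 TPM, as was Trim10 (2.08 ± 0.488 TPM), which passed at 2.17-fold higher in replicate 2 (1.64 to 2.89). Of the 25 members, 23 lay above the median ratio of all genes.

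The median of the activated list minus that of the repressed list, on the log2(TPM + 1) scale, was -2.07 in replicate 1 and 0.05 in replicate 2 (mean -1.01 ± 1.498, SD, n = 2). The value of replicate 2 was close to 0, and it was -0.53 from CPM, -0.73 without the globin genes and -0.53 without Gfi1b and Zfpm1, but 0.05 with a pseudocount of 0.1 and 0.14 over members with a TPM of at least 1, while replicate 1 was negative in each of these settings. Among 10000 random lists of expressed genes of the same size, the activated list lay at percentile 92.8 in replicate 1 and 100 in replicate 2, and the repressed list at 99.98 and 99.9.

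**Figure D2:**
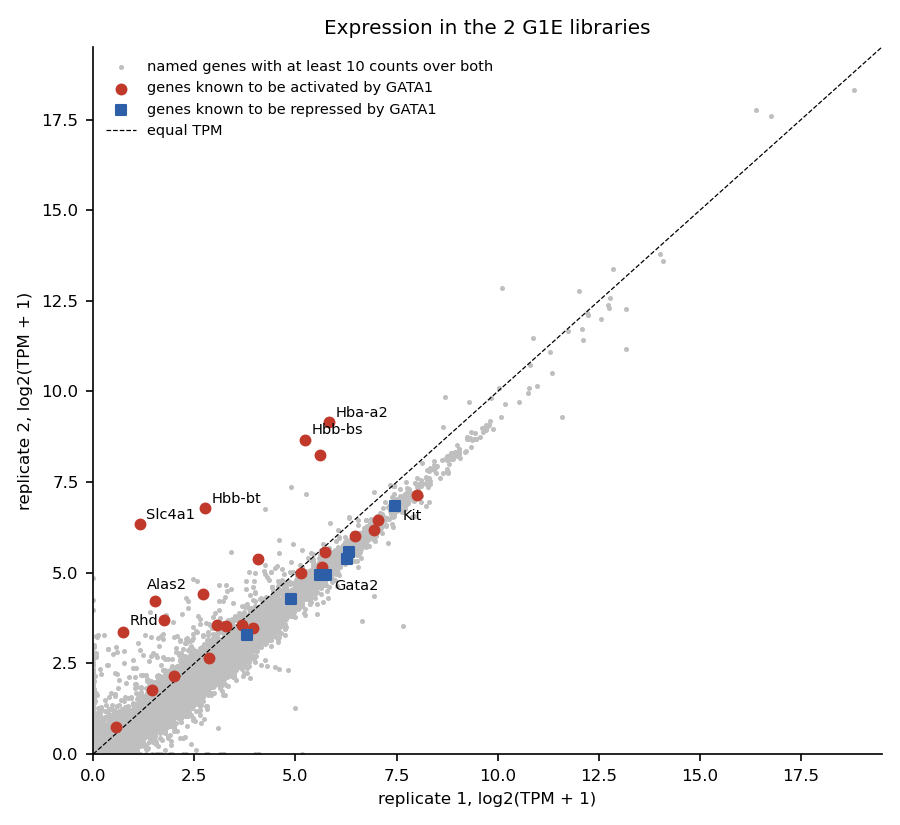
Each point is a gene, placed by log2(TPM + 1) in replicate 1 (horizontal) and replicate 2 (vertical), for 11795 named genes with at least 10 counts over both libraries. Some GATA1-activated genes such as Slc4a1 (1.22 and 79.9 TPM) lie above the line of equal TPM, and others such as Car1 (257 and 140 TPM) below it. GATA1-repressed genes such as Kit lie with the bulk.

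Some globin, haem and membrane genes were higher in replicate 2, in lists that share members with the activated list. Over these 4 lists 18 of 50 distinct tested genes were higher there. Of 10 measured globin genes, 5 were detected, and 4 of 5 tested were higher in replicate 2, led by Hbb-bt (28.4-fold, 95% interval 22.5 to 36.4). The embryonic globins Hba-x, Hbb-bh2 and Hbb-y had 0 counts in both libraries, and Hbb-bh1, named after its value was seen, had 0 and 3. Of 16 haem genes, 5 were higher in replicate 2, among them the mitochondrial iron carrier Slc25a37 (3.92-fold, 3.71 to 4.15), while Cpox (252 ± 95.2 TPM, SD, n = 2), Blvrb (77.1 ± 28.8 TPM) and Fech (76.1 ± 17.5 TPM) were the most abundant and did not pass. Hmox1 (1.73 ± 0.099 TPM), Blvra (3.04 ± 0.827 TPM) and Flvcr1 (3.30 ± 0.849 TPM) were the lowest.

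Of 21 red cell membrane and blood group genes, 8 were higher in replicate 2 and 0 in replicate 1. Aqp1, a water channel, had 1 count against 496, a ratio of 556 with a wide interval (99.3 to 22004). Tmod1, an actin-capping protein, was 2.24-fold higher (1.71 to 2.95). Rhag (109 ± 31.8 TPM), Cd47 (82.1 ± 26.2 TPM), Epb41 (68.4 ± 3.87 TPM) and Xk (52.3 ± 19.8 TPM) were the most abundant and did not pass the test. Adjusted over the list alone, the counts were 4 of 5 for globins, 5 of 16 for haem and 8 of 21 for membrane genes. All 4 erythroid lists lay at percentile 100 of random lists matched on expression. Scaled to total counts, 10 activated, 4 globin, 3 haem and 7 membrane genes were higher in replicate 2, and the haem list's median log2 ratio was -0.14. Scaled to spike-ins, all genes had a median log2 ratio of -4.49 and the activated list one of -3.58, and calls turned to 1 higher in replicate 2 and 20 in replicate 1 for activated genes, 0 and 2 for globins, 0 and 16 for haem and 3 and 17 for membrane genes.

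**Figure D3:**
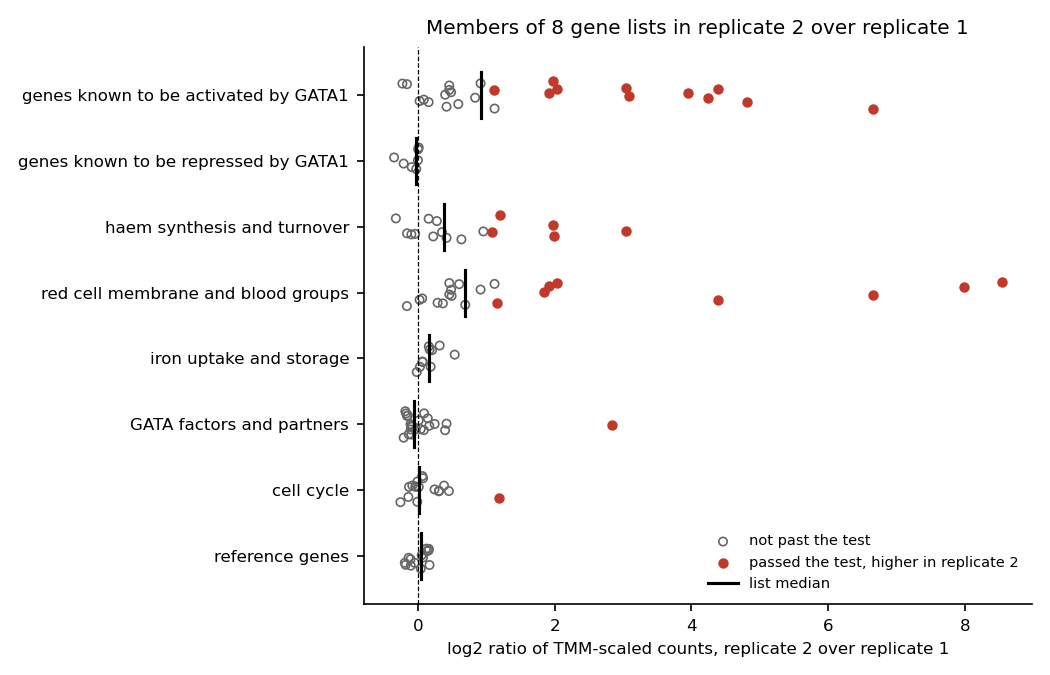
Log2 ratio of TMM-scaled counts, replicate 2 over replicate 1 (horizontal axis), for tested members of 8 gene lists, with filled points for genes that passed the test and a bar at each list's median. The activated list has 11 filled points of 25 and a median of 0.92, and the repressed list has none and a median of -0.02.

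Few iron, cell cycle and reference genes passed the test between the libraries. The iron store subunits Ftl1 (517 ± 122 TPM, SD, n = 2) and Fth1 (434 ± 133 TPM), the transferrin receptor Tfrc (75.9 ± 12.6 TPM) and Aco1 (23.5 ± 6.02 TPM) led the iron list, in which 0 of 10 tested genes passed, although 9 lay above the median ratio of all genes and the list at percentile 99.61 of matched random lists. Slc40a1 (7.51 ± 0.0778 TPM) and Steap3 (4.55 ± 1.03 TPM) were low, and Hfe had 0 counts. All 17 cell cycle genes were detected, led by Mki67 (135 ± 16.6 TPM), Mcm3 (110 ± 45.2 TPM), Ccna2 (79.6 ± 35.6 TPM) and Top2a (77.6 ± 15.6 TPM), and Birc5, named after its value was seen, was the only one to pass, 2.27-fold higher in replicate 2, a call that ended when libraries were scaled to total counts (0 of 17). Of 14 reference genes 0 passed.

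Cytokine receptor and signalling genes were led by Kit, and 2 of 9 tested members passed the test. Csf2rb (30.05 ± 10.2 TPM, SD, n = 2), Stat5a (27.7 ± 8.48 TPM) and Jak2 (24.0 ± 7.74 TPM) followed Kit, and Csf1r, Epo and Flt3 had 0 counts. Csf2ra (36 counts in replicate 1 and 3 in replicate 2) and Il3ra (33 and 12), named after their values were seen, were higher in replicate 1. In the apoptosis list Mcl1 (53.7 ± 20.9 TPM), Trp53 (43.6 ± 18.3 TPM), Bak1 (39.1 ± 13.3 TPM) and Cdkn1a (37.8 ± 10.1 TPM) were highest, Bcl2 (0.625 ± 0.346 TPM) and Bad (2.17 ± 1.02 TPM) were low, Pmaip1 had 0 counts, and 0 of 12 tested genes passed (1 with libraries scaled to total counts). Egr1 (36.8 ± 7.95 TPM) and Ddit3 (36.0 ± 12.1 TPM) led the immediate early and stress genes, of which 0 of 6 passed.

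Markers of other cell types were mostly at or near 0. All 18 lymphocyte markers, such as Cd3d, Cd3e and Cd3g, and all 12 pluripotency markers, such as Dppa3 and Esrrb, had 0 counts in both libraries. Of 11 fibroblast and endothelial markers, 9 had 0 counts, with 3 counts of Pecam1 and 2 of Kdr the most seen. Exceptions were the mast cell protease Cpa3 (38.1 ± 18.9 TPM, SD, n = 2), Hdc (3.31 ± 0.608 TPM), the myeloid transcription factor Spi1 (15.7 ± 7.06 TPM) and the platelet genes Pf4 (11.3 ± 2.11 TPM), Itga2b (5.75 ± 2.95 TPM) and Ppbp (2.35 ± 1.51 TPM). Of tested markers, 1 of 7 for megakaryocytes (2 with total counts), 2 of 4 for granulocytes and macrophages and 0 of 3 for mast cells, basophils and eosinophils passed. Gp1ba (32 and 10 counts) and Cd68 (17 and 1) were higher in replicate 1 and Adgre1 (1 and 15) in replicate 2, and Gp1ba and Adgre1 were named after their values were seen.

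Structural RNAs were abundant, with Rn7sk at 14897 ± 3521 TPM (SD, n = 2), Rpph1 at 3341 ± 123 TPM, Rmrp at 1071 ± 37.9 TPM and Malat1 at 903 ± 8.09 TPM. After TMM scaling, their ratios of replicate 2 over replicate 1 were 1.06, 1.40, 1.53 and 1.63, below the 2-fold limit. H19 and Meg3 had 0 counts, and 0 of 8 tested long and structural RNAs passed. The line is labelled male, but the Y-linked genes Eif2s3y, Kdm5d and Uty had 0 counts in both libraries. Ddx3y had 0 and 64 counts, and Xist 2 and 0.

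Across all genes the libraries had a Pearson r of 0.982 and a Spearman rho of 0.935 on log2(TPM + 1), computed across genes, which are not independent replicates. Of these 43346 genes only 13603 and 13688 had any count in replicates 1 and 2. Over genes with a TPM of at least 1 in at least 1 library r was 0.942, and rho was not computed there. The common biological coefficient of variation was 26.3% over 11518 genes. Against counting error, 604 of 11902 tested genes were higher in replicate 2 and 260 in replicate 1, a test that compares these libraries and not conditions. Scaled to total counts the split was 394 and 1013, with the median gene at -0.52, and scaled to spike-ins it was 36 and 11608. The spike-in amount put into each library is not given in the sources used here, so the spike-in scaling cannot be read as RNA content. A negative binomial exact test, with the common dispersion estimated from these same 2 libraries, called 263 and 33. The differences under test thus set the spread they were judged against, so these calls do not exceed an independent replicate spread.

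The largest differences among genes with a mean count of at least 100 included genes absent from a library, ranked after adding 0.5 counts. Exact lower bounds give another order, with 99.3 for Aqp1 against 89.4 for Btnl10. Btnl10 (0 and 296 counts), Cacna1g (0 and 266) and Ptp4a3 (0 and 257) were at least 111-fold, 99.4-fold and 96.0-fold higher in replicate 2, against a floor of 3 counts, with exact 95% lower bounds of 89.4, 80.3 and 77.5 once the counting error of replicate 2 was included. Gm16867 (0.5 and 338 estimated counts) and Hist2h3c1 (0 and 280) also ranked here. The deposited TPM credibility intervals of Gm16867 were 0.0981 to 1.02 in replicate 1 and 4.33 to 7.91 in replicate 2. Those of Hist2h3c1, 8.01e-06 to 2.13 and 0.000411 to 5.61, overlapped. Hist2h3c1 (chromosome 3, 96246685 to 96248509) lies within Gm20634 (96245554 to 96248509) on the same strand. Gm20634 had 341 and 50.9 estimated counts and ranked in the other direction, so they may not be separate differences. In the other direction Gm10259 ranked first, 148-fold higher in replicate 1 against the floor of 3 counts (exact lower bound 120, for counting error only). Its deposited TPM credibility interval started at 10.5 in replicate 1 and ended at 3.14 in replicate 2. The uncertain assignment of its reads thus allows a much smaller difference. Gm28439 (13.8-fold), Hist1h2aj (12.7-fold), Gm14440 (8.97-fold) and Gm20634 (5.96-fold) followed. The deposited TPM credibility intervals of Gm14440 (1.32 to 5.31 and 0.0294 to 2.71) and Gm20634 (4.78 to 8.37 and 0.474 to 6.00) overlapped. Those of Gm28439 and Hist1h2aj did not, but Gm28439 was identical to the mitochondrial mt-Nd4 over 876 nucleotides in BLAST. The estimated counts of these 5 genes higher in replicate 1, of Gm16867 and of Hist2h3c1 were not all whole. Reads shared with similar genes were thus split among them, and their values are uncertain.

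Spike-in transcripts made up 0.00162% of the estimated count in replicate 1 (95% Clopper-Pearson interval 0.00149 to 0.00177) and 0.0255% in replicate 2 (0.0250 to 0.0260). Their totals were 514 and 10351 counts, and 17 and 25 of the 96 ERCC transcripts had counts. ERCC-00130, the most counted, had 195 and 4175 counts.

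**Figure D4:**
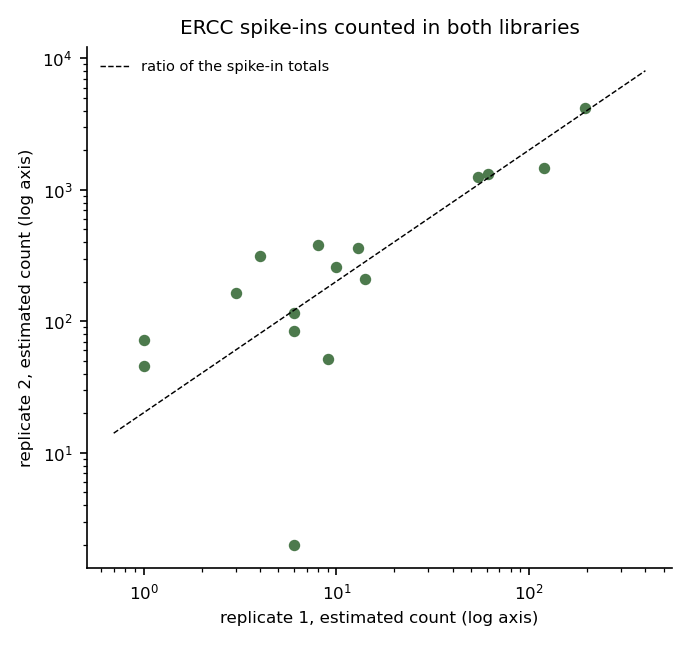
Estimated counts of the 16 ERCC spike-ins counted in both libraries, replicate 1 (horizontal, log axis) against replicate 2 (vertical, log axis), with a dashed line at the ratio of the spike-in totals, 20.1. Ratios scatter on both sides of the line.

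Estimated isoform shares were close in the libraries for most of the erythroid regulators. The main transcript of Gata1 held 97.0% ± 2.90 of the gene's TPM (SD, n = 2), that of Tal1 97.4% ± 0.636, that of Lmo2 94.4% ± 1.31, and Klf1 had a single annotated transcript. Gata2 had transcripts of 83.9% ± 0.495 and 16.1% ± 0.495. Kit was divided between transcripts of 53.6% ± 0.544 and 36.0% ± 1.63, and Runx1 among several, the first at 32.1% ± 5.25. These shares are model estimates over annotated transcripts only, 3 of them for Gata1. A share therefore does not show that a full-length transcript was made, in a line labelled as lacking Gata1.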

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

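Entries named only by a number, which no comparison used, had 7 estimated counts in replicate 2, above the 3 that a count of 0 allows. What these entries are was not identified, and no explanation was tested.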

How the results depend on the processing

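Most alternatives were chosen before the data were examined, while the whole-count and 400-count filters, the correlation over coding genes only, the list median without Gfi1b and Zfpm1, and leaving out a library for detected genes, were chosen after seeing the data. With a main value of 864 genes differing between libraries (604 higher in replicate 2, 260 in replicate 1), total counts gave 1407 (394 and 1013), spike-in totals 11644 (36 and 11608), a filter of 100 counts 260 (225 and 35), the negative binomial test 296 (263 and 33) and a filter of 400 counts 94 (87 and 7), the filters by testing fewer genes. Whole estimated counts alone gave 169 higher in replicate 1. Detected genes numbered 5040 at a TPM of 5, and r was 0.942 over expressed genes. The Gata2 to Gata1 log2 ratio was 1.25 with a pseudocount of 0.1 and 2.03 from CPM, which take no account of gene length. Without spike-in and mitochondrial entries, Gm42418 took 64.7% and nuclear protein-coding genes 31.4%, and by TPM nuclear protein-coding genes took 15.9% and mitochondrial mRNAs 5.61%. The posterior mean isoform share was 96.7% for Tal1 and 90.4% for Lmo2. Except where a filter or unit changes what is counted, the cause was not tested. Leaving out a library gave -2.07 to 0.0493 for the activated minus repressed list median, so its sign reversed without replicate 1 on that scale, while replicate 2 alone was -0.53 from CPM, -0.73 without globin genes and -0.53 without Gfi1b and Zfpm1, but 0.05 with a pseudocount of 0.1 and 0.14 over members with a TPM of at least 1. With 2 libraries each value left lies within 1 SD of the mean by construction, so leaving out a library shows stability for no other mean. The other 62 main alternatives stayed within 1.5-fold for counts and the coefficient of variation, 0.01 for r and 1 SD for means. They include values with a library left out, and a rise of detected genes from 9161 to 13401 by posterior mean TPM. Of 100 alternatives for single lists 25 moved, 15 of them on rescaling TPM over nuclear protein-coding genes. Those that did not move also include values with a library left out. No paired analysis was possible because the labels give 1 group.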

Other observations

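All tests of explanations in this part were chosen only after the results they bear on were seen, and the genes named here were chosen after their values were seen.

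Some genes outside the lists were picked by eye from the 604 that were higher in replicate 2, with no test of enrichment. Slc43a1 had 3 counts in replicate 1 and 732 in replicate 2, Slc14a1, the Kidd blood group urea transporter, 2 and 329, and Trim58, a ubiquitin ligase of late erythroblasts, 0 and 155. Slc6a9, a glycine transporter, was 14.1-fold higher (95% interval 9.86 to 20.7), Tmcc2 7.93-fold (6.69 to 9.44) and Stom 5.09-fold (4.16 to 6.26). Hemgn (3.33-fold), Ache (3.03-fold), E2f2 (2.72-fold) and Ube2o (2.67-fold) were also higher in replicate 2. The antiviral gene Rsad2 (0 and 229 counts) also passed the test.

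Tcrg-C1, a T cell receptor gamma constant gene, had 104 and 54.9 TPM from 896 and 637 counts, while Trac, Trbc1 and Trbc2 had 0. It was the only one of 7 T cell receptor constant genes with any count. All 64 counts of Ddx3y were on a single transcript of 664 nucleotides annotated as a retained intron.

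In the first pattern, late erythroid genes higher in replicate 2, counting and amplification noise would take no account of gene function, but 18 of 50 tested members of the 4 erythroid lists were called higher in replicate 2 and 0 in replicate 1, and 0 of 10000 random lists matched on expression had as many calls, the highest having 7. These 4 of the 20 lists are those whose calls defined the pattern, so the comparison is not an independent test of it. For RNA of whole blood, spleen or marrow in replicate 2, only 4 of 34 lymphocyte, granulocyte and macrophage markers had enough counts to be tested, of which 1 was called higher there (Adgre1, 1 and 15 counts) and 1 lower (Cd68). All 18 lymphocyte markers, S100a8 and S100a9 had 0 counts in replicate 2, but the level that such RNA would need is not known, so it stays open. A minority of more mature erythroid cells in the culture, or their RNA in the library, may account for the pattern but was not settled: the iron list lay at percentile 99.61 of matched random lists, below the structural RNA list at 99.93, every GATA1-repressed gene stayed within 2-fold of all genes, and Gata1 had a ratio of 0.912 (95% interval 0.821 to 1.01). Cells or RNA of the related ER4 line, which is derived from G1E, carries an inducible GATA1 and shares the linked extraction protocol, were not tested as a source and stay open for every late erythroid ratio, as the design names no difference between these libraries.

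The second pattern is the 20.1-fold higher spike-in count in replicate 2. A single common factor with counting error only is argued against by the ratios of 16 spike-ins with at least 30 counts, which differed from each other (chi-square 70.0, 15 degrees of freedom, p = 4.39e-09). Ratios of those counted in replicate 1 ran from 5.78 to 78.5, around a median of 23.1. A common factor with added amplification noise was not tested, nor was any biological explanation.

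The third pattern is that mt-Atp6 and Gm10925 moved in opposite directions. mt-Atp6 went from 13345 counts in replicate 1 to 120994 in replicate 2 (log2 ratio 3.35), and Gm10925, a pseudogene on chromosome 1 (24613974 to 24614651, GRCm38), from 110017 to 37588 (log2 ratio -1.38). The transcripts were identical over 678 nucleotides in BLAST, and their summed count had a log2 ratio of 0.53. Reads shared between mt-Atp6 and its nuclear copy, divided differently in each library, may thus account for both moves, and no biological explanation was tested.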
